A study of Saccharomyces cerevisiae with 48 samples.

How the data were processed

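ChIP-exo tags were analysed for 22 groups of budding yeast samples, 48 samples in total. Chromosomally tagged Paf1C subunits (Ctr9, Paf1, Rtf1, Rtf1-E104K, Cdc73, Leo1), Rad6 and Bre1 with and without RTF1, Rpb3, Spt4 and Spt5, and H2B and H2BK123ub in wild type came from cells in rich medium. The other 7 groups came from an rtf1 deletion strain in medium without tryptophan, carrying plasmids with an ADH1 promoter and full-length Rtf1, its HMD (residues 63 to 152) or HMD-E104K: the 3 HSV-tagged proteins, and H2B and H2BK123ub with the RTF1 and HMD plasmids. Per the labels, cells were grown at 30 °C and crosslinked with 1% formaldehyde for 15 min. The antibody to H2B differed between wild type and the plasmid strains, and the antibody to H2BK123ub was the same.

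The values used were whole counts of tags per position and strand, deposited by the authors as 1 file per group with the replicates pooled and the first reads shifted by 6 bp, as the file names state. The submitters' processing notes name BWA 0.7.9a and bcl2fastq 2.16 and the builds sacCer3 and R64. Filters on mapping quality and on duplicate reads were not given in the sources used here. Groups of 2 samples made up 19 of the files, groups of 3 made up 2 and a group of 4 made up 1. Depth ran from 1.26 M tags (HMD-E104K) to 65.0 M (Bre1), and a gene at 20 tags is known far less closely than a strongly bound gene, so genes named singly had to reach a mean of 100 tags. This floor counts tags, not positions. Bre1 in the rtf1 deletion held 64.9 tags per occupied strand position and H2BK123ub with the HMD 26.98. Because replicates were pooled, no spread between cultures and no p-value could be computed, and values are the authors' pooled values.

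Tags on the 16 nuclear chromosomes outside the ribosomal DNA were counted over open reading frames and expressed per kb and per M (mega) such tags. Of 6002 protein-coding genes, 5118 of at least 300 bp that have a symbol were used. Loci changed in any strain were left out of the medians of all genes and of the genes named, and long genes within 2000 bp of them or overlapping another gene were left out along genes. No spike-in, input or mock sample was used here, so absolute levels were not compared between libraries. Concentration on active genes was the log2 of the median density over the active list divided by that over the silent list, compared between groups in 8 comparisons. For H2BK123ub it was computed on the ratio to H2B of the same strain. In 7 further comparisons the log2 ratio of the first to the last 500 bp was compared with Rpb3 over the 514 genes highest in Rpb3 of 2056 genes of at least 1500 bp. The 300 bp after the stop codon were compared with the last 500 bp for 135 of these with no gene within 500 bp downstream.

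Gene ratios were log2 with a pseudocount of 1 density unit, for genes with a mean of at least 20 tags. Ranges over genes are the central 95% of 1000 resamplings of genes. Intervals of single genes are 95% binomial counting intervals. Each list median was set beside 10000 random lists of the same size and matched density, as a description of these libraries. A difference of at least 1.5-fold was counted as larger. Where the median of all genes moved by more than 0.1, lists and genes were also given relative to it.

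The active list joined 17 glycolysis genes and 130 genes with ribosomal protein symbols. The symbol pattern also caught RPP1, which encodes a subunit of RNase P and RNase MRP. The silent list was 40 genes of meiosis and sporulation. Further lists were glucose-repressed genes, histone genes, ribosome biogenesis, chaperones and heat shock, oxidative phosphorylation, amino acid biosynthesis, sulfur and methionine, the phosphate regulon, the iron regulon and alpha-specific genes. Of the oxidative phosphorylation list 27 genes were measured. The a-specific list had fewer than the required 4 measured genes and was left out. The lists and comparisons were fixed before the data were examined. Genes named were panel genes, at most 12 per comparison with the highest and lowest of the panel among them, the 5 highest and 5 lowest genes with a mean of at least 100 tags that overlap no other gene, and the extremes of each list. The changed loci themselves served only as label checks.

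Alternatives were at most 10 tags per position and strand, each strand alone, other active and silent lists (glycolysis alone, the 10% of genes highest in Rpb3, glucose-repressed genes), open reading frames without 150 bp at each end, summed tags, thinning to equal totals, end windows that scale with gene length, all long genes, a pseudocount of 5, other tag minimums and centring on all genes. Thinning to equal totals followed by at most 1 tag per position and strand was added after seeing the data. A planned lag between forward and reverse tags was not computed. The methods were tested on simulated data. In the Rad6 comparison, over 5067 genes, median log2 sizes of 0.57, 1.00 and 1.99 were recovered for simulated 0.58, 1.00 and 2.00, and −0.51 for a simulated difference in concentration of −0.50. The other comparisons between groups recovered −0.52 to −0.45 for it. Of 100 unchanged lists 3 to 9 fell outside the central 95% of random lists, where 5 were due, the most for HMD against full-length Rtf1 over 4720 genes. Over 2077 genes with simulated end ratios of 0.00 and −0.30 the same values were recovered. Counting intervals held the true ratio in 96.8% and 94.6% of 1000 draws. Computation used python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.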

Results

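The series mapped, by ChIP-exo in budding yeast, where the Paf1 complex (Paf1C), its subunit Rtf1, the ubiquitylation factors Rad6 and Bre1, RNA polymerase II and H2B ubiquitylated on lysine 123 (H2BK123ub) crosslink to the genome. In ChIP-exo an exonuclease trims immunoprecipitated DNA to the crosslink border, and each tag marks 1 trimmed end. The 48 samples fell into 22 groups, of which 19 pooled 2 samples, 2 pooled 3 and 1 pooled 4. Each group was 1 pooled library holding the authors' pooled counts, so no difference could be set against a spread between replicates. Intervals given for genes are 95% counting intervals and cover counting error only, since tags without molecular identifiers are not independent molecules. Ranges given for gene lists are the central 95% of resampled genes and describe how far genes differ, not how far cultures do.

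Depth ranged widely, and is given in M (mega, as in Mb). The Paf1C libraries held 10.4 M tags for Ctr9, 7.59 M for Rtf1, 6.07 M for Paf1, 4.76 M for the Rtf1-E104K mutant, 4.09 M for Cdc73 and 3.53 M for Leo1. Rpb3, a subunit of RNA polymerase II, had 15.3 M tags, and the elongation factors Spt4 and Spt5 had 35.4 M and 33.7 M. Rad6 had 6.87 M tags with RTF1 and 1.57 M without it, while Bre1 had 65.0 M and 50.7 M. In the rtf1 deletion strain carrying plasmids, full-length HSV-tagged Rtf1 had 7.87 M tags, the histone modification domain (HMD, residues 63 to 152) had 2.5 M and HMD-E104K had 1.26 M. H2B had 12.7 M tags in wild type, 8.65 M with the RTF1 plasmid and 6.99 M with the HMD plasmid, and H2BK123ub had 30.1 M, 7.11 M and 21.2 M in the same strains. Many tags shared a position: the Bre1 library of the rtf1 deletion held 64.9 tags per occupied strand position, against 1.23 in the matching Rad6 library.

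RTF1 itself (chromosome VII, 41498 to 43174) showed the labelled genotypes. In the Rad6 library of the rtf1 deletion it held 0 tags, against a density of 81.7 tags per kb per M over its HMD-coding part (41684 to 41953) in the Rad6 library with RTF1. In the Bre1 library of the deletion the HMD-coding part held 257 tags on 2 strand positions (density 18.9), against 152 with RTF1, and the coding sequence after it held 1 tag. In the plasmid strains the HMD-coding part stood at 6511 with full-length Rtf1, 3675 with HMD and 5195 with HMD-E104K. More than 50 bp beyond it the density was 5342, 9.65 and 2.74, so the truncated genes were on the plasmids that the labels name. In wild-type H2B, Ctr9, Paf1, Rtf1, Rtf1-E104K, Cdc73 and Leo1 libraries, whose strains keep RTF1 on the chromosome, the HMD-coding part lay between 85.5 and 213.5, and it was 68.2 in Rpb3, 81.3 in Spt4, 86.9 in Spt5 and 184.6 in wild-type H2BK123ub. The pheromone receptor genes STE2, active in a cells, and STE3, active in alpha cells, were set against the labelled mating type. They followed it in 14 of 14 libraries other than those of H2B, H2BK123ub and the HMD, and in 20 of all 22. In HMD-E104K and in H2B with the HMD plasmid, both labelled a, STE2 stood at 0.928 and 0.937 of STE3. Rpb3 (a cells) had 771 at STE2 and 3.70 at STE3, whereas Rtf1 (alpha cells) had 26.1 and 460.2.

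Paf1C, like the polymerase, was concentrated on ribosomal protein and glycolysis genes. Concentration was taken as the median density over 147 active genes (130 matching ribosomal protein symbols and 17 of glycolysis) relative to the median over 40 silent genes of meiosis and sporulation. This fold was 39.4 for Rtf1, 32.8 for Ctr9, 31.6 for Paf1, 28.4 for Leo1, 27.4 for Rpb3 and 21.4 for Cdc73. Spt5 had 12.1 and Spt4 10.8. With 1 tag per strand position the order changed, to 20.97 for Leo1, 20.5 for Rtf1, 17.5 for Cdc73, 16.6 for Paf1, 13.1 for Rpb3, 9.52 for Ctr9, 3.13 for Spt5 and 2.69 for Spt4. Depth was not matched for this order. Its lowest members, Spt4, Spt5 and Ctr9, had the most occupied strand positions of those listed (12.11 M, 10.98 M and 5.52 M), so the order is not free of depth. The ubiquitin ligase Bre1 had 6.79 and its partner, the conjugating enzyme Rad6, 3.37, while H2B in wild type had 1.21. PMA1, the plasma membrane proton pump (chromosome VII, 479910 to 482666), held 2246 tags per kb per M in Rtf1, 1349 in Rpb3, 430.2 in Bre1 and 415.9 in Rad6. SPO11, which makes meiotic DNA breaks (chromosome VIII, 62961 to 64157), held 25.4, 10.1, 58.0 and 81.1 in the same libraries. Across genes, which are not independent replicates, Spearman correlations were 0.86 to 0.98 among the 10 pairs of Paf1C subunits, 0.77 to 0.87 between these and Rpb3, and 0.95 for Spt4 and 0.97 for Spt5 with Rpb3.

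**Figure D1:**
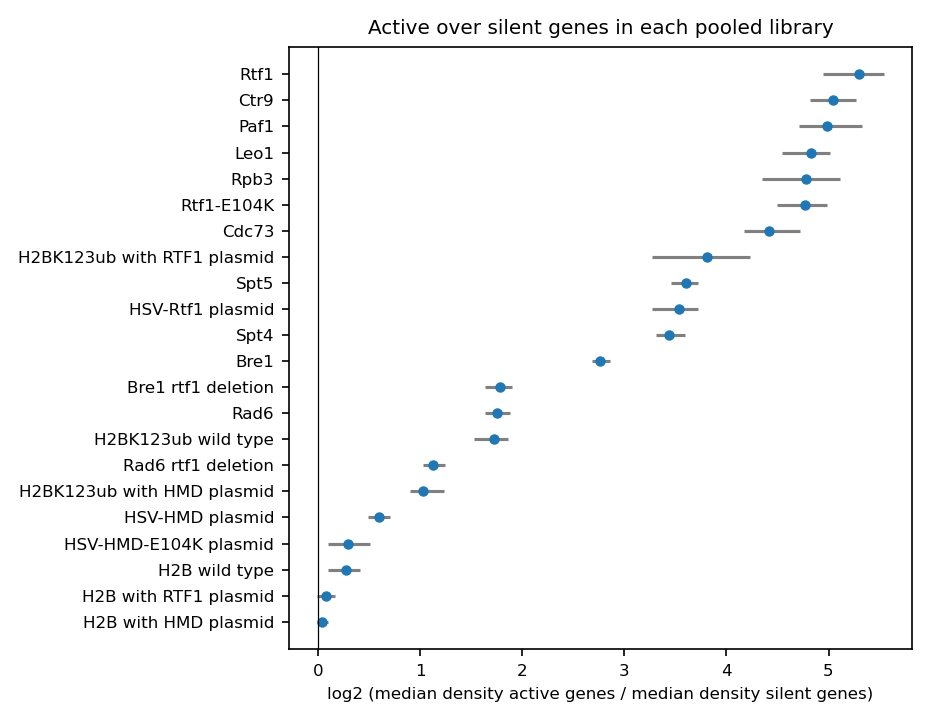
Each point is the log2 ratio of the median density over the active genes to that over the silent genes in 1 pooled library, and each line is the central 95% of values when the genes of both lists are resampled. Rtf1 stands highest at 5.30, Bre1 and Rad6 lie at 2.76 and 1.75 and at 1.78 and 1.12 in the rtf1 deletion, and HMD lies at 0.60.

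Rad6 was less concentrated on active genes when RTF1 was deleted. This comparison asks whether the conjugating enzyme needs Rtf1 to reach transcribed chromatin. At ribosomal protein genes the median log2 ratio of deletion to RTF1 was −0.58, with 129 of 130 below 0 and 58 lower by at least 1.5-fold. Random lists of the same density had a median of −0.36. In the panel PHO84, the high-affinity phosphate transporter (chromosome XIII, 24037 to 25800), was lowest, at 286.4 against 458.8 (log2 −0.68, interval −0.79 to −0.57). ILV5, of branched-chain amino acid synthesis (chromosome XII, 838066 to 839253), was 393.1 against 580.9, PMA1 291.3 against 415.9, and the glycolytic dehydrogenase TDH3 379.9 against 525.0. GAL7, a galactose gene silent in glucose, was highest in the panel, at 98.5 against 83.5, with an interval from −0.01 to 0.49.

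Other gene groups differed among themselves. Histone genes had a median of −0.46, against −0.39 for random lists of the same density, led by HHF2 at −0.82 and HTB1 at −0.63, while the linker histone gene HHO1 was at 0.23. Glycolysis was at −0.30, against −0.27 for such random lists, with 15 of 17 genes below 0, the lowest being the mutase gene GPM1 at −0.67. The phosphate regulon was at −0.25, against −0.04 for random lists, with 10 of 12 below 0 and SPL2, a regulator of phosphate uptake, at −1.03. Glucose-repressed genes were at 0.16 with 14 of 17 above 0, among them the invertase gene SUC2 at 0.32. The other lists ran from −0.05 for ribosome biogenesis, −0.02 for chaperones and −0.02 for the iron regulon, through 0.00 for sulfur, 0.03 for amino acid biosynthesis and 0.04 for oxidative phosphorylation, to 0.08 for meiosis and 0.21 for 4 alpha-specific genes. Among the lowest genes, beside SPL2, were AHT1 (−1.10) and ARG80 (−0.91), a regulator of arginine genes. The 5 highest, GGA1 (1.34), PEP7 (1.32), GPI8 (1.28), SKP1 (1.23) and SBE2 (1.22), all lay on chromosome IV between 1112480 and 1191732, inside a stretch with more tags throughout in the deletion library. The fold of active over silent genes was 2.18 without and 3.37 with RTF1, a log2 difference of −0.63 (range −0.74 to −0.51). The difference was −0.33 with glycolysis genes alone as the active list and −0.29 with the 10% of genes highest in Rpb3. HIS3, labelled as deleted in both strains, held 118.3 in the Rad6 library with RTF1 and 0 tags in the other, so the strains differed at that locus too.

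Bre1 was likewise lower at ribosomal protein genes without RTF1, in strains of its own. The comparison asks whether the ligase, like Rad6, depends on Rtf1 for its place on active genes. Ribosomal protein genes had a median of −0.70, with 127 of 130 below 0 and 90 lower by at least 1.5-fold, against −0.46 for random lists of the same density. RPL17A (−1.23) and RPS30B (−1.22) were lowest. PHO84 was again the lowest panel gene, at 245.3 against 524.3 (log2 −1.09, interval −1.12 to −1.07), and ILV5 was 396.8 against 744.6. The ribosomal stalk gene RPP0 was 251.9 against 434.4, and the chaperone gene HSC82 158.5 against 234.3. SPO11 was highest in the panel, at 98.1 against 58.0 (log2 0.75), and ADH2, a glucose-repressed alcohol dehydrogenase gene, was at 0.70.

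Among the other groups in Bre1, glucose-repressed genes had a median of 0.40 with 16 of 17 above 0, and only the gluconeogenic gene FBP1 was below, at −0.11. The silent meiosis list was at 0.21 with the spore wall gene CDA1 at 1.11. Histone genes were at −0.33, with HTB1 at −0.70, and glycolysis was at −0.28, with GPM1 at −0.78, where random lists of the same density were at −0.41 and −0.30. Alpha-specific genes, expressed in these alpha strains, were all lower, at a median of −0.52 against −0.50 for random lists, with MF(ALPHA)1 at −0.63. The lowest genes included LEU1 (−1.39), of leucine synthesis, and SNU13 (−1.44), of small nuclear and nucleolar particles, beside DMO1 (−2.02), SNO3 (−1.66) and FYV12 (−1.37). The highest were the seripauperin gene PAU10 (1.53), the thiamine gene THI5 (1.46), the hexose transporter gene HXT15 (1.38), SWC7 (1.33) and SPI1 (1.27). The deletion library held 64.9 tags per occupied strand position, so these single genes may rest on few positions. Active over silent genes stood at 3.43-fold without and 6.79-fold with RTF1, a log2 difference of −0.99 (range −1.14 to −0.86). It was −0.47 with glycolysis genes alone and −0.48 with the 10% of genes highest in Rpb3.

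**Figure D2:**
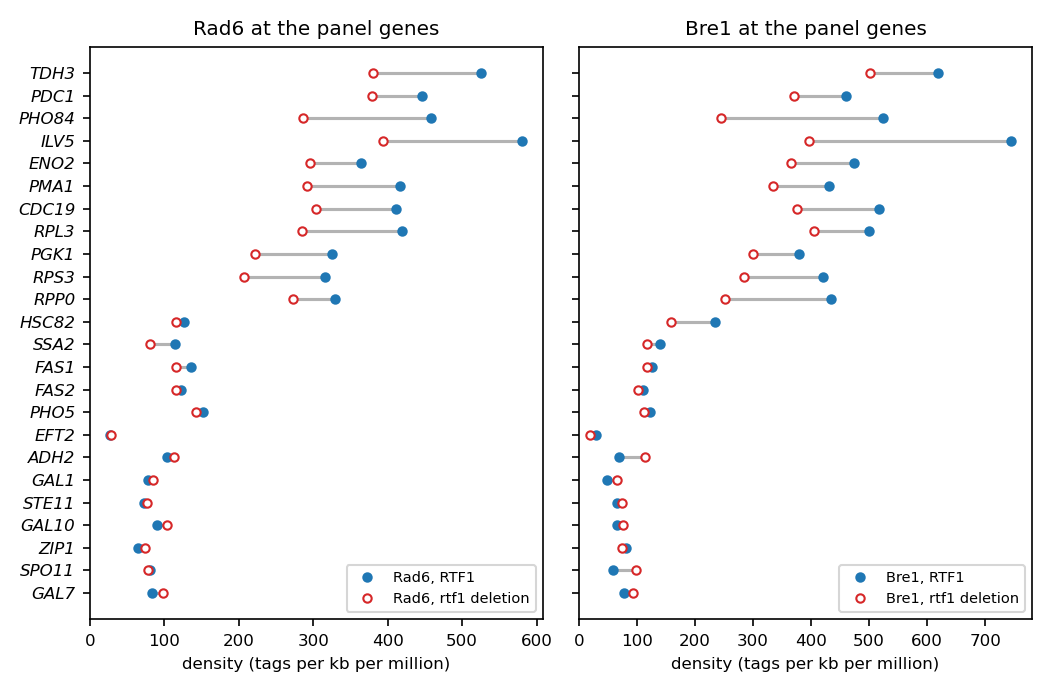
Density in tags per kb per M of Rad6 (left) and Bre1 (right) over each panel gene, ordered by Rpb3 density, with RTF1 (filled points) and in the rtf1 deletion (open points), 1 pooled library per point. ILV5 and PHO84 show the widest gaps, 580.9 to 393.1 and 458.8 to 286.4 for Rad6 and 744.6 to 396.8 and 524.3 to 245.3 for Bre1, whereas GAL7 is higher in both deletion libraries.

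The E104K substitution in the HMD left Rtf1 on active genes, with a concentration that was lower when all tags were counted. The comparison asks whether a change in the HMD alters where Rtf1 binds. The glycolysis list had a median of −0.47, with 16 of 17 below 0, and random lists of the same density had −0.30. The isozyme genes TDH2 (−0.89) and ENO2 (−0.85) were lowest, and ENO2, at 993.0 against 1797, was also the lowest panel gene (chromosome VIII, 451327 to 452640). Ribosomal protein genes were at −0.35, equal to random lists of the same density, with 125 of 130 below 0. Histone genes were at −0.47 (HHF1 −0.88), the iron regulon was at −0.49 (the ferroxidase gene FET3 −1.0) and alpha-specific genes were at −0.71 (SAG1 −0.79). Ribosome biogenesis genes went the other way, at 0.14 with 49 of 65 above 0 and NOP14, of the small-subunit processome, at 0.57.

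Single genes moved further in both directions under E104K. These are the extremes of many genes, in a library of only 0.91 M occupied strand positions at 5.23 tags each. Sampling of few positions could give such values, and this was not tested. The lowest were IRC6 (−1.68), MZM1 (−1.61), HIT1 (−1.57), SNM1 (−1.45) and URM1 (−1.36), a ubiquitin-like modifier gene. The highest were SEO1 (1.61), the meiotic cohesin gene REC8 (1.5), MIP6 (1.45), ARG3 (1.43), of arginine synthesis, and GPG1 (1.36). GAL7 was the highest panel gene, at 0.45 (interval 0.13 to 0.81). PMA1 was 1493 against 2246. Concentration on active genes was 27.3-fold in Rtf1-E104K and 39.4 in Rtf1, a log2 difference of −0.53 (range −0.75 to −0.31). This size depended on the gene lists and tags used, being −0.86 with glycolysis genes alone, −0.26 with glucose-repressed genes as the silent list, −0.23 on the forward strand and −0.19 after thinning to equal totals and 1 tag per strand position, the last chosen after seeing the data. With 1 tag per strand position and no thinning no loss was seen, at 20.9-fold in Rtf1-E104K and 20.5 in Rtf1. That setting sets 0.91 M occupied strand positions beside 2.75 M, and the cap acts more strongly on the fuller library. It therefore cannot decide whether the loss is absent.

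The HMD alone, expressed without the rest of Rtf1, was far less concentrated on the gene classes where the full-length protein was highest. The comparison asks whether the domain by itself is recruited as the intact protein is. The median of all genes was 0.15, and lists are given relative to it. Glycolysis genes were at −2.65, histone genes at −2.29, ribosomal protein genes at −2.10 and chaperone genes at −1.22. Before that shift these were −2.49, −2.14, −1.95 and −1.07, against −1.51, −1.61, −1.57 and −0.57 for random lists of the same density. PMA1 was the lowest panel gene, at 297.7 against 2455 (interval −3.11 to −2.98 before that shift), and TDH3 was 277.4 against 1957. The silent meiosis list was at 0.90, with 39 of 40 genes above the median of all genes, and the alpha-specific list, silent in these a cells, was at 1.00. GAL7 was the highest panel gene, at 107.0 against 38.3, close to its H2B density of 114.0 in the HMD strain.

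The 5 lowest genes were SED1 (0.116 of the full-length level), a cell wall glycoprotein gene, PMA1 (0.122), the ribosomal protein gene RPL8A (0.124), the aldolase gene FBA1 (0.141) and the peroxiredoxin gene AHP1 (0.142). The 5 highest were SHR5 (4.15), of protein palmitoylation, RSO55 (3.67), UTR5 (3.66), AIM26 (3.48) and THI13 (3.27). Among the other lists, also relative to all genes, ribosome biogenesis was at −0.48, oxidative phosphorylation at −0.59, amino acid biosynthesis at −0.34, sulfur at 0.15, the phosphate regulon at 0.45, the iron regulon at 0.52 and glucose-repressed genes at 0.54. The fold of active over silent genes was 1.52 for HMD and 11.6 for full-length Rtf1, a log2 difference of −2.93 (range −3.10 to −2.70). Wild-type H2B stood at 1.21-fold and H2B with the HMD plasmid at 1.03, and no mock was used. Weaker recruitment of the HMD can therefore not be told apart from a lower yield of its precipitation. Each library was scaled to its own total, so the higher values at silent genes do not show binding there. At PHO84 full-length Rtf1 itself held 75.02 in the plasmid strain, grown without tryptophan, against 2018 for the chromosomally tagged Rtf1 grown in rich medium.

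E104K within the isolated HMD went with a further small loss at active genes. The comparison asks whether the residue matters for what the domain retains. The median of all genes was −0.16, and relative to it histone genes were at −0.22, ribosomal protein genes at −0.19 and glycolysis genes at −0.15. Before that shift, 31 of 130 ribosomal protein genes were lower by at least 1.5-fold and 1 was higher. PMA1 was the lowest panel gene, at 156.1 against 297.7 (log2 −0.93, interval −1.07 to −0.79). RPL3 was 148.3 against 245.4 and the decarboxylase gene PDC1 214.0 against 343.3, while PHO84 was highest, at 143.4 against 112.1 (log2 0.35). The meiosis list changed direction with the scaling, from −0.06 to 0.10 relative to all genes. The lowest genes were GOS1 (−1.34), RPS14B (−1.31), MRP1 (−1.27), CIT2 (−1.23) and the casein kinase gene CKA2 (−1.19), and the highest IRC13 (1.82), DMO1 (1.40), AIM26 (1.34), YAP6 (1.21) and VPS24 (0.95). Active over silent genes stood at 1.22-fold with E104K and 1.52 without it, a log2 difference of −0.31 (range −0.49 to −0.10). It was −0.11 on the reverse strand and −0.15 with glucose-repressed genes as the silent list. Wild-type H2B stood at 1.21-fold and H2B with the HMD plasmid at 1.03. HMD-E104K was thus close to the level of H2B, and no mock was used. A loss tied to the residue cannot be told apart from a lower yield of that precipitation.

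H2B itself was alike in the strains with full-length Rtf1 and with the HMD. List medians of HMD against RTF1 plasmid ran from −0.12 for glycolysis to 0.06 for alpha-specific genes, and the ribosomal protein list was at −0.01. ENO2 was the lowest panel gene (−0.21) and TDH3 the highest (0.37, interval 0.17 to 0.58). Across all genes named by the rule the extremes were TOS6, a cell surface gene, at −0.72 and SHU2, of DNA repair, at 0.54. The log2 difference in concentration on active genes was −0.04 (range −0.11 to 0.05).

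H2BK123ub, in contrast, was spread far more evenly with the HMD than with full-length Rtf1. The comparison asks where the mark is placed when only the HMD is present, and each gene was taken as H2BK123ub over H2B of the same strain. The silent meiosis list was higher with HMD at 40 of 40 genes, with a median log2 ratio of 1.52, and the silent alpha-specific list at 4 of 4, with a median of 2.26. Random lists of the same density had 0.78 and 0.46, so genes of like density shared a part of these shifts. GAL7 was the highest panel gene (2.66), with H2BK123ub at 85.0 against 12.9, and SPO11 and ZIP1, of meiotic chromosome pairing, were both at 1.45. Ribosomal protein genes had a median of −0.71, with 80 of 130 lower by at least 1.5-fold, against −0.41 for random lists of the same density. RPL3 was the lowest panel gene (−1.58), with H2BK123ub at 83.5 against 248.3 (chromosome XV, 444686 to 445849).

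Genes did not all move alike, within lists or between them. The glycolysis list was at −0.45, yet TPI1 (−1.28) and HXK1 (1.00) lay far apart, and PGK1 was at 0.20. Oxidative phosphorylation genes were at −0.61, with ATP7, of ATP synthase, at −1.97, and histone genes were at −0.42. The phosphate regulon was at 0.52, with PHM6 (3.82) and SPL2 (2.65) highest. In full-length Rtf1 from the plasmid this regulon stood at only 1.68 times the silent list, against 11.35 times for ribosomal protein genes. Chaperone and heat shock genes were at −0.30, with 15 of 25 below 0 and HSP12 (2.51) the highest. The lowest genes were TEF1 (−3.36), ASR1 (−2.54), SDC1 (−2.35), of the histone methyltransferase COMPASS, GIS2 (−2.34) and the prefoldin gene GIM3 (−2.24). The H2BK123ub library with the HMD held 26.98 tags per occupied strand position, so single genes may rest on few positions. How tags at near-identical gene copies were assigned was not given in the sources used here, which bears on TEF1, the PAU genes and paired ribosomal protein genes. The highest were the subtelomeric genes PAU19, PAU11, PAU16 and PAU20, which held 844, 329, 452 and 243 tags with HMD and 2, 0, 1 and 0 with full-length Rtf1, too few for a ratio, and MAM1 of the meiotic monopolin complex, at 116.3 against 2.63. The fold of active over silent genes was 2.04 with HMD and 13.2 with full-length Rtf1, a log2 difference of −2.70 (range −3.15 to −2.33), and −1.51 with glucose-repressed genes as the silent list. Because each library was scaled to its own total, the values give where the mark lay, not how much of it the cells held.

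Full-length Rtf1 from the plasmid went with a steeper H2BK123ub profile than in wild type. Here strain, medium, RTF1 expression and H2B antibody all differed, so the comparison only sets the reference strain beside wild type. All 130 ribosomal protein genes were higher with the plasmid, at a median of 1.10, against 0.22 for random lists of the same density. RPL28 (2.15), RPS31 (2.14), RPL37A (1.83), RPL22A (1.70) and the ribosome-associated factor gene STM1 (1.78) were the 5 highest, and RPL3 led the panel at 1.63. Oxidative phosphorylation was at 0.71, with ATP14 at 1.38. The meiosis list was at −1.0, with 39 of 40 below 0, and the phosphate and iron regulons were at −1.07 and −0.70, with SPL2 at −2.84 and TIS11 at −1.89. GAL7 was the lowest panel gene (−1.73). PAU20, PAU24, PAU11 and PAU16 held 0, 0, 0 and 1 tags with the plasmid and 374, 237, 263 and 286 in wild type, and the autophagy gene CIS1 was at −3.77 with 5 tags against 460. The fold of active over silent genes was 13.2 with the plasmid and 2.65 in wild type, a log2 difference of 2.32 (range 2.03 to 2.69).

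**Figure D3:**
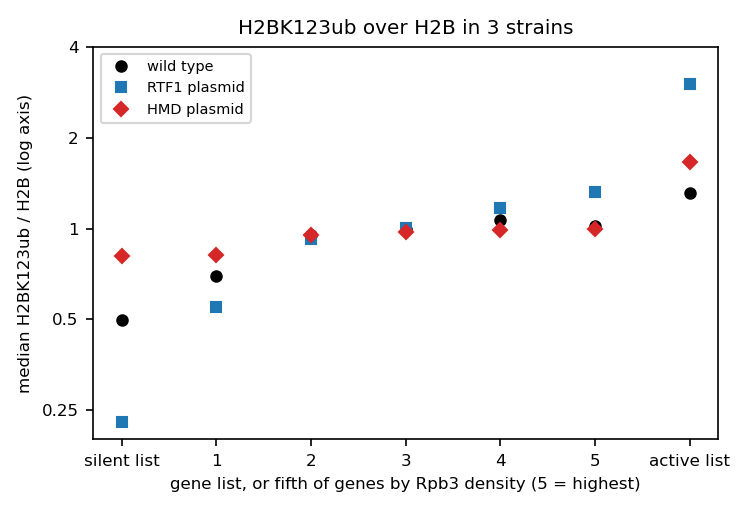
Median ratio of H2BK123ub to H2B density, on a log axis, over the silent list, 5 groups of genes ordered by Rpb3 density and the active list, in 3 strains with 1 pooled library per mark. From the silent to the active list the medians run from 0.228 to 3.01 with full-length Rtf1 on a plasmid. With the HMD they run from 0.813 to 1.66, and in wild type from 0.497 to 1.32.

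Paf1C, Spt4 and Spt5 were compared with Rpb3 along genes to ask where each factor joins and leaves the polymerase. Rpb3, Spt4 and Spt5 carried TAP tags, and the Paf1C subunits HA or Myc tags in other strains. Tag, antibody and strain therefore differ along with the factor. After the stop codon Paf1C dropped where the polymerase stayed high. Over 135 highly transcribed genes with no neighbour close downstream, the 300 bp after the stop had a median log2 ratio to the last 500 bp of the gene of −0.18 for Rpb3, −0.26 for Spt4 and −0.29 for Spt5. Ctr9 was at −1.31, Rtf1 at −1.11, Paf1 at −1.06, Leo1 at −0.99 and Cdc73 at −0.94. Gene by gene, Ctr9 was lower than Rpb3 at 132 of the 135 genes, Rtf1 at 128, Paf1 at 126, Leo1 at 113 and Cdc73 at 108, while Spt4 and Spt5 were lower at 92 and 89. The drop was not particular to Paf1C, since wild-type H2B was at −1.29, lower than Rpb3 at 132 genes, and wild-type H2BK123ub was at −1.51. At the other end, the highest bin of the mean profile over 514 long genes was sought from the start codon on. For Rpb3 it was the first 50 bp, at 207.8, and for Spt5 50 to 99 bp, at 190.1. The Rpb3 bin lies at the edge of the search, which left out bins before the start codon, so it need not be a peak. Rtf1, Paf1 and Ctr9 peaked at 300 to 349 bp, at 241.6, 235.5 and 238.8, Leo1 at 350 to 399 bp, at 212.3, and Cdc73 at 400 to 449 bp, at 214.0. Spt4, unlike Spt5, was highest in the last 50 bp of the window, from 1450 bp on, at 159.4. Before the stop codon of the 135 genes it reached 181.7, so the highest bin at an edge of the window does not mark a peak.

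**Figure D4:**
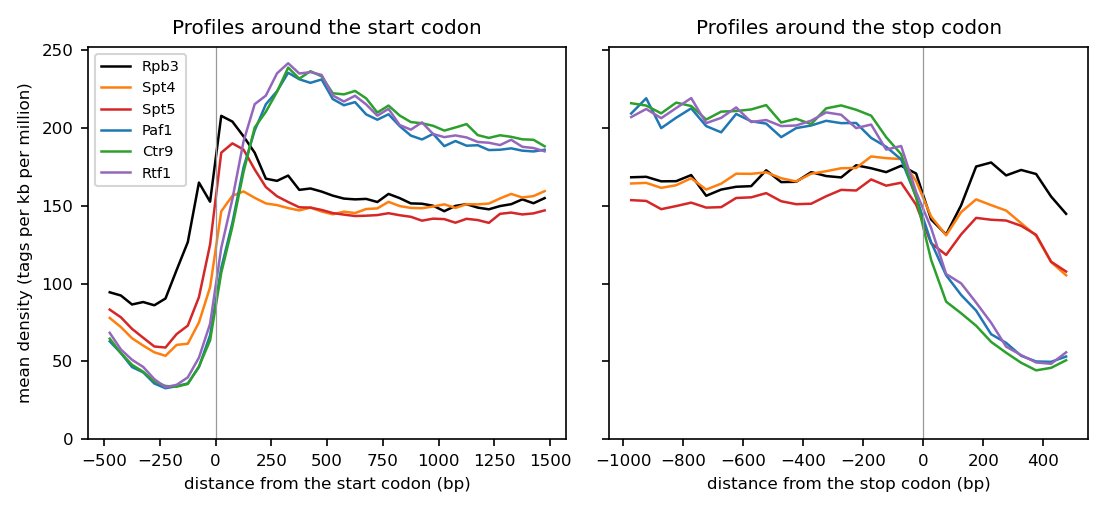
Mean density in tags per kb per M in 50 bp bins around the start codon of the 514 long genes highest in Rpb3 (left) and around the stop codon of the 135 of these with no gene within 500 bp downstream (right), each line 1 pooled library. From the start codon on, Rpb3 is highest in the first bin, at 207.8, and Rtf1 at 300 to 349 bp, at 241.6. The 3 Paf1C subunits drop after the stop codon where Rpb3, Spt4 and Spt5 stay high.

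Between the first and last 500 bp of these long genes the factors differed less. The median log2 ratio of first to last was 0.15 for Rpb3, and the difference from Rpb3 was −0.33 for Leo1 (range −0.37 to −0.27), −0.31 for Spt4 (−0.33 to −0.27), −0.30 for Cdc73 (−0.39 to −0.23), −0.11 for Ctr9 (−0.16 to −0.06) and −0.06 for Paf1 (−0.10 to −0.02). Rtf1 at −0.01 (−0.05 to 0.03) and Spt5 at −0.02 (−0.05 to 0.01) did not differ from Rpb3 beyond the range over genes. Over all long genes the differences were −0.19 for Leo1, −0.20 for Spt4, −0.15 for Cdc73, −0.01 for Ctr9 and 0.03 for Paf1, so the Paf1 value changed sign. With summed tags in place of medians Paf1 was at 0.04 and Ctr9 at −0.03.

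In these libraries Paf1C was also shared out among gene groups differently from the polymerase. Tag, antibody and strain again differed between Paf1C and Rpb3, and all comparisons used the same Rpb3 library. The medians of all genes against Rpb3 were 0.27 for Paf1 and Leo1, 0.25 for Cdc73, 0.24 for Ctr9, 0.21 for Rtf1 and 0.20 for Spt4 and Spt5, and lists are given relative to these. Ribosome biogenesis genes were at 0.50 for Cdc73, 0.40 for Ctr9 and Rtf1 and 0.38 for Paf1 and Leo1, against −0.21 for Spt4 and −0.20 for Spt5. The ribosome assembly gene ERB1 was highest in Rtf1, at 0.96 before that shift. Histone genes were lower in all of these, at −1.37 for Cdc73 and Leo1, −0.93 for Spt4, −0.88 for Paf1, −0.76 for Ctr9, −0.72 for Spt5 and −0.67 for Rtf1. The iron regulon was lower too, from −1.42 for Paf1 to −0.86 for Spt4. The shared Rpb3 library held medians of 916.2 at histone genes and 170.8 at the iron regulon. A high value in that library alone would lower every factor, so the agreement between factors is not independent. Ribosomal protein genes were at 0.32 in Rtf1, 0.24 in Ctr9, 0.23 in Paf1, 0.05 in Leo1, 0.01 in Cdc73, −0.25 in Spt5 and −0.36 in Spt4. Glycolysis in Paf1 had no stable direction, at −0.03 unscaled and 0.36 with at most 10 tags per strand position, and in Rtf1 it was 0.16 unscaled and −0.06 relative to all genes. Chaperone genes in Ctr9 likewise were at 0.03 and −0.21.

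Some of the largest single-gene differences from Rpb3 were at mating-type genes. In Rtf1, from alpha cells, the 5 highest were MF(ALPHA)1 (8.00), STE3 (6.62), AFB1 (4.33), MF(ALPHA)2 (4.06), all of alpha-cell identity, and the serine deaminase gene CHA1 (3.36). The lowest were STE2 (−4.83) and HMRA1 (−4.80), of a-cell identity, with FIT2 (−3.94), API2 (−3.89) and IRC13 (−3.89). In Paf1, from a cells like Rpb3, CHA1 (3.17) was highest, followed by BSC1 (2.78) and PRM7 (2.07), and the iron regulon gene TIS11 was among the 5 lowest (−2.36). In the panel TDH3 was lowest for every Paf1C subunit relative to all genes, from −1.30 in Leo1 to −0.17 in Ctr9, where the unscaled value was 0.06. For Spt4 the lowest panel gene was PHO84 (−0.94 relative to all genes) and for Spt5 it was TDH3 (−0.81), and the silent gene SPO11 was highest for both, at 1.68 and 1.66.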

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

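The loci in this part were taken from the labels, and no test in it was chosen after its result was seen. At 30 loci that the labels give as deleted, 23 held no tags and 26 at most 3. The other 4 held more than a count of 0 allows, which is why they are given here. They serve in the report only as checks of the labels.

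HIS3 (chromosome XV, 721946 to 722608) stood at 118.3 tags per kb per M in the Rad6 library with RTF1, from 537 tags on 245 strand positions, or 1.30 times the median gene. The label gives HIS3 as deleted, and the Rad6 library without RTF1 held 0 tags there. In the Leo1 library HIS3 stood at 6.83, from 16 tags on 5 strand positions. The HMD-coding part of RTF1 stood at 18.9 in the Bre1 library of the rtf1 deletion, from 257 tags on 2 strand positions. MET17, the gene also called MET15, stood at 0.343 in the Rpb3 library, from 7 tags on 3 strand positions. No cause was tested for any of the 4.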

How the results depend on the processing

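In this part only thinning followed by 1 tag per position and strand, and the same without thinning, were chosen after seeing the data. A value counted as reversed only if its sign changed and it had stood apart to begin with, a comparison by a range over genes that leaves out 0 and a list by lying outside the central 95% of random lists. Of 80 alternatives for concentration on active genes 21 left the value within its counting error, 59 moved it and 0 reversed it. For the first against the last 500 bp the numbers were 8, 32 and 2 of 42, for list medians 667, 301 and 4 of 972, and for Spearman correlations with Rpb3 26, 16 and 0 of 42. All of these alternatives kept the direction for Rad6 (−0.70 to −0.29), Bre1 (−1.11 to −0.47), Rtf1-E104K (−0.86 to −0.19), HMD (−3.24 to −2.15), HMD-E104K (−0.33 to −0.11), H2BK123ub with HMD (−2.93 to −1.51) and H2BK123ub with the RTF1 plasmid against wild type (1.68 to 2.53). Outside this count, 1 tag per position and strand without thinning did not keep it for Rtf1-E104K, at 20.9-fold against 20.5 in Rtf1. There the libraries were unequal, with 0.91 M and 2.75 M occupied strand positions, so this setting cannot decide on the direction. For H2B, whose range includes 0, only 7 of 10 alternatives kept the sign (−0.16 to 0.06). Values that moved follow by setting, and the cause was not tested. Reverse strand: Rad6 −0.58, Bre1 −1.10, Rtf1-E104K −0.66, HMD −2.85, HMD-E104K −0.11, H2BK123ub with HMD −2.53. Forward strand: Bre1 −1.0, Rtf1-E104K −0.23, HMD −2.88, HMD-E104K −0.23, H2B 0.01, H2BK123ub with HMD −2.93 and against wild type 2.53. Glycolysis genes as the active list: Rad6 −0.33, Bre1 −0.47, Rtf1-E104K −0.86, HMD −3.24, H2B −0.16, H2BK123ub with HMD −2.23 and against wild type 1.70. Glucose-repressed genes as the silent list: Rad6 −0.70, Bre1 −1.10, Rtf1-E104K −0.26, HMD −2.66, HMD-E104K −0.15, H2B 0.06, H2BK123ub with HMD −1.51 and against wild type 1.81. The genes highest in Rpb3 as the active list: Rad6 −0.29, Bre1 −0.48, Rtf1-E104K −0.47, HMD −2.15, H2B −0.10, H2BK123ub with HMD −2.35 and against wild type 1.68. Trimmed gene ends: Rad6 −0.69, Bre1 −1.11, Rtf1-E104K −0.41, HMD −2.88, H2B 0.01, H2BK123ub with HMD −2.64 and against wild type 2.27. Summed tags: Rad6 −0.58, Bre1 −0.87, Rtf1-E104K −0.46, HMD −3.07, H2BK123ub with HMD −2.18 and against wild type 1.97, and along genes Paf1 0.04 (reversed), Ctr9 −0.03, Cdc73 −0.20, Leo1 −0.23, Rtf1 0.08, Spt4 −0.26, Spt5 0.00. At most 10 tags per position and strand: Bre1 −0.73, H2BK123ub with HMD −2.18 and against wild type 2.21, and along genes Ctr9 −0.10, Cdc73 −0.27, Leo1 −0.30, Rtf1 0.01, Spt4 −0.27. Thinned to the smallest total: H2BK123ub with HMD −2.64 and against wild type 2.25, and along genes Leo1 −0.32, Spt4 −0.30, Spt5 −0.03. Thinned, then 1 tag per position and strand: Rad6 −0.56, Bre1 −0.68, Rtf1-E104K −0.19, HMD −2.59, H2BK123ub with HMD −1.94 and against wild type 2.01, and along genes Ctr9 −0.10, Cdc73 −0.22, Leo1 −0.27, Rtf1 −0.04, Spt4 −0.19, Spt5 −0.04. End windows that scale with gene length: Paf1 −0.03, Ctr9 −0.07, Cdc73 −0.22, Leo1 −0.25, Spt4 −0.24, Spt5 −0.03. All long genes: Paf1 0.03 (reversed), Ctr9 −0.01, Cdc73 −0.15, Leo1 −0.19, Rtf1 0.05, Spt4 −0.20, Spt5 0.01. Among lists that stood apart from random lists, 4 reversed: glycolysis in Paf1 against Rpb3 at 0.36 with at most 10 tags per position and strand, and, relative to all genes, meiosis in HMD-E104K at 0.10, chaperones in Ctr9 against Rpb3 at −0.21 and glycolysis in Rtf1 against Rpb3 at −0.06. Lists that did not stand apart also changed sign relative to all genes, such as chaperones in Paf1 (0.09 to −0.17), Cdc73 (0.08 to −0.18) and Leo1 (0.08 to −0.20). No paired analysis was possible because replicates were pooled in the files, and for the same reason leaving out a replicate or a replicate block was not run. Depth limits single genes in HMD-E104K (1.26 M tags) and Rad6 without RTF1 (1.57 M), the fewest by tags, and in Cdc73 (0.42 M), HMD-E104K (0.55 M) and Leo1 (0.65 M), the fewest by occupied strand positions. Next by positions were Bre1 without RTF1 (0.78 M), H2BK123ub with the HMD (0.79 M) and Rtf1-E104K (0.91 M), where the same limit holds.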

Other observations

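Rad6 and Bre1 also crosslinked to genes outside the messenger RNA class. The median over 275 tRNA genes, transcribed by RNA polymerase III, was 229.3 in Rad6 and 144.7 in Bre1, or 3.29 and 2.34 times the silent list. In the rtf1 deletion these were 170.6 and 114.6, or 2.33 and 1.58 times. A signal at tRNA genes was not particular to these, since Rpb3 had 2.37 times the silent list there, wild-type H2BK123ub 2.01 times and the Paf1C subunits 1.36 to 2.17 times. Over 76 snoRNA genes Rpb3 stood at 50.98 times, Rtf1 at 33.9, Bre1 at 5.62 and Rad6 at 2.98 times the silent list.

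Tags of the isolated HMD were also distributed along genes differently from those of full-length Rtf1. Over 514 long transcribed genes the median ratio of promoter to gene body density was 0.678 for HMD and 1.17 for HMD-E104K, against 0.244 for full-length Rtf1 from a plasmid. The promoter was the higher of the regions at 126 genes for HMD and 297 for HMD-E104K. A high promoter share was not particular to the HMD, since Rpb3 stood at 0.576, with the promoter higher at 136 genes. HMD and HMD-E104K were only 1.52-fold and 1.22-fold concentrated on active genes, and no mock was used. The ratio can therefore not be read as placement of the protein.

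Of the tests that follow, those of PCR duplicates, precipitation yield, a loss alike at all active genes, dilution with bulk H2B, amplified positions and loss of Rtf1 itself were chosen only after the results were seen, and so were the ranges over genes used for the gene-by-gene test and for Bre1 in the chromosome IV stretch.

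The first pattern is the lower concentration of Rad6 and Bre1 on active genes without Rtf1. Thinning left −0.67 for Rad6 and −0.99 for Bre1, but it lowers active and silent genes alike, so these values say little about depth. Thinning followed by 1 tag per position and strand left −0.56 and −0.68, against −0.63 and −0.99 as first computed. This argues against PCR duplicates as the whole source, though the Bre1 difference shrank, so a part of it may go with them. Among the 1015 genes highest in Rpb3, how far the deletion library departed from a straight-line fit on the RTF1 library was hardly correlated with the Rtf1 to Rpb3 ratio, at a Spearman of −0.05 (range −0.11 to 0.02) for Rad6 and −0.06 (−0.13 to 0.00) for Bre1, which argues only against a loss beyond that fit where Rtf1 is high for the Rpb3 present. A lower yield of the precipitations stays open, since the share of excess left at tRNA over that at active genes was only 0.22 in log2 (0.08 to 0.35) for Rad6 and 0.04 (−0.26 to 0.24) for Bre1. So does a loss alike at all active genes, since the share left at glycolysis over that at ribosomal protein genes was 0.53 (0.08 to 0.79) and 0.62 (0.28 to 0.79) over the silent list, but 0.29 (−1.46 to 0.63) and 0.43 (−1.33 to 0.65) over a background shaped like wild-type H2B and 0.29 (−1.83 to 0.67) and 0.43 (−1.06 to 0.61) over one shaped like HMD-E104K, and so do, with RNA polymerase II in the rtf1 deletion not analysed here, a change in transcription and a difference between cultures.

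The second pattern is the flatter H2BK123ub profile with the HMD than with full-length Rtf1. Thinning left −2.64, which again says little about depth. Thinning followed by 1 tag per position and strand left −1.94, against −2.70 as first computed, which argues against PCR duplicates as the whole source. Were the HMD profile that of full-length Rtf1 diluted with bulk H2B, its log2 ratio of first to last 500 bp would lie between theirs. It was 0.17 above the higher of them (0.04 to 0.28), a range over genes only. This ratio also moved between other libraries, at −0.05 for H2B in wild type and 0.15 with the RTF1 plasmid. For H2BK123ub it was 0.12 and 0.41 in the same strains. With 1 pooled library per group the difference can therefore not decide on dilution. With the HMD the active list still stood above the silent list, at 1.03 in log2 (0.87 to 1.19), against 1.41 (1.24 to 1.57) in wild type. That list is mostly ribosomal protein genes. Glycolysis genes with the HMD stood at 1.12 times the silent list in H2BK123ub and 1.14 times in H2B, so they showed no such preference. What places the mark and its total amount stay open.

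The third pattern is a stretch of chromosome IV, from 1102184 to 1206383 and 104.2 kb long, with more tags in the Rad6 library without RTF1. Its 42 genes, HIM1 to ESF1, were all higher, at a median of 1.03 in log2 against 0.01 on the rest of the chromosome, and it is flanked by elements of 5269 bp each, YDR316W-B and YDR365W-B. An extra copy in those cells is likely, since the 7 windows without genes stood at 0.95, and 0.94 with 1 tag per position and strand argues against a few amplified positions. Loss of Rtf1 itself is argued against by Bre1, at −0.04 relative to the median of all genes in the same stretch. Its range over genes, −0.10 to 0.24, was taken without that shift and with the pseudocount. Whether the strain carries such a copy was not checked, and when it would have arisen stays open. No gene of the active or silent list lies inside the stretch.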
